A study of Homo sapiens with 16 samples.

How the data were processed

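Total RNA from 16 cultures of the breast cancer line MDA-MB-231 was measured on Affymetrix human expression arrays, 1 array per culture, in 4 groups of 4 biological replicates. Biotin-labelled cRNA had been made from 2 µg of total RNA. The values are intensity, the deposited linear MAS5 signal per probe set. Per the submitters' processing notes the signals came from MAS5, whose version is not given in the sources used here. The values themselves show that the authors scaled each array to the same 2% trimmed mean of about 250 and took no logarithm. Detection calls were not used here. The sources describe the samples as biological replicates and say nothing more of how separate the cultures were, so p-values measure the spread between these samples.

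Of 22283 probe sets 68 are controls and were left out of the comparisons, which leaves 22215. By the array's annotation 19065 of these carry 1 gene symbol, 1043 several and 2107 none. For gene-level work the probe set with the highest mean over the 16 arrays was taken for each gene among those with 1 symbol, which gave 11963 genes. Signals were used as scaled by the authors and taken to log2 after adding 16, with no filter on dim probe sets. A fold on this scale understates the change of dim genes. Array medians on the log2 scale ran from 6.51 to 6.75, a range of 0.24, under the limit of 0.5 at which centred values would have been given beside every result. Errors are the SD between replicates for signals and the SE of the fit for log2 differences.

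All 16 arrays were fitted together with limma 3.58.1 in R 4.3.3 (group means, lmFit, eBayes with an intensity trend, 12 residual degrees of freedom). There were 5 comparisons, resistant against parental, paclitaxel-treated against untreated resistant, and bexarotene plus paclitaxel against each of the other groups. A probe set was called at a Benjamini-Hochberg adjusted p below 0.05 in a two-sided moderated test, adjusted within each comparison over all probe sets, and the count at 2-fold or more is given beside it. The 29 gene lists hold 714 genes. They cover drug efflux transporters, tubulins, microtubule regulators, retinoic acid receptor, liver X receptor and PPAR targets, interferon-stimulated genes and antigen presentation. They also cover mitosis, S phase, apoptosis, p53 targets, mesenchymal genes, epithelial genes, luminal breast, blood cell and fibroblast markers, matrix proteases, and cholesterol synthesis. The rest are inflammatory genes, the unfolded protein and integrated stress response, hypoxia and glycolysis, NRF2 targets, TGF-beta and YAP targets, metallothioneins, breast stem cell markers, cancer-testis antigens, ribosomal proteins and oxidative phosphorylation. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. The number of arrays, 4 per group, limits the precision of every value.

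The design, the lists and the naming rule were fixed before the data were examined. In the first 3 comparisons the rule takes the 8 genes with the highest and the 8 with the lowest log2 difference among those called, with a brighter-group mean above the median of all values and no overlap between the groups. In the other comparisons it takes 4 on each side. It adds from each list called the 3 members with the smallest adjusted p, allows 2 to 4 members of any list described, and fixes 25 genes of drug transport, tubulin, cell cycle, retinoid and interferon biology to be given as values. Genes outside the rule are named as such. The share of genes with opposite signs in resistant against parental cells and in bexarotene plus paclitaxel against paclitaxel, and the correlation of these differences across genes, were tested with a two-sided exact permutation of the 8 labels of the latter arrays (70 arrangements). Neighbouring genes were taken by the gene order of assembly GRCh38.p14, in runs of 15 genes, against 200 shuffled gene orders. This order held only the 6855 genes on the autosomes or chromosome X with a mean log2 signal above the median of all probe sets. Dimmer measured genes between them were skipped and are left out of the runs and their counts.

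Alternatives were quantile normalisation, median centring, pseudocounts of 1 and 64, leaving out the 40% dimmest probe sets, no intensity trend, a robust prior, array weights, replicate number as a block, a fit of the compared groups alone, 1 probe set or the mean of all probe sets per gene, camera with an estimated correlation, limma's fry, and leaving out each array in turn. Chosen after the data were seen were spike-in brightness as a covariate, the 9 arrays with dimmer and the 7 with brighter spike-in controls, and leaving out the 2 arrays with the highest 18S ribosomal RNA signal. The fit was tested on simulated data with 200 changed probe sets among 22215 in each of 20 simulations. The number was raised from 1 to 20 after the first simulation had been seen. It recovered from 53.6% to 57.1% of 2-fold changes and from 91.9% to 93.7% of 4-fold changes in the 5 comparisons, and from 4.58% to 5.42% of its calls were false. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.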

Results

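RNA from 16 cultures of MDA-MB-231 cells was measured on Affymetrix expression arrays, 1 array per culture. MDA-MB-231 is a breast cancer line that lacks the oestrogen receptor. The cultures fell into 4 groups of 4 biological replicates. Parental cells had no drug selection. Resistant cells had been selected over 8 cycles of 10 days, each with 3 days of 30 nM paclitaxel, a drug that stabilises microtubules, and 7 days without it. Resistant cells were then kept for 3 months on vehicle, on the same paclitaxel cycle, or on that cycle together with 1 µM bexarotene. Bexarotene was given on all 10 days of each cycle, unlike paclitaxel. The vehicle group is called resistant cells here. Bexarotene activates the retinoid X receptors, nuclear receptors that pair with the retinoic acid, liver X and peroxisome proliferator-activated receptors. After the authors' scaling, the 2% trimmed mean signal was 250 on every array, and array medians ran from 75.1 to 91.3. Replicates of a group correlated between 0.945 and 0.975 across probe sets on the log2 scale. The precision of all values is limited by the number of arrays, 4 per group.

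The first question was how the resistant cells differed from the parental line. Parental cells are listed without a selection or treatment period. Time in culture therefore cannot be told apart from resistance in comparisons with them. Genes of varied function rose, among them several for secreted proteins. The signal of LCN2, which encodes the iron-siderophore carrier lipocalin 2, was 1723 ± 81.9 (SD, n = 4) in resistant cells and 94.3 ± 53.01 in parental cells, a log2 difference of 4.12 ± 0.23 (SE, adjusted p = 1.71e-10). Complement component C3 rose from 76.5 ± 26.9 to 1327 ± 294, and the neuroendocrine granule protein SCG2 from 88.4 ± 21.5 to 1458 ± 155. The membrane metalloprotease ADAM28, near background in parental cells, rose by 4.09 ± 0.13 on the log2 scale, from 2.37 to 5.27 over the other settings, and CYTIP, a cytohesin-binding protein of blood cells, by 3.45 ± 0.15. INHBA, which encodes the activin A subunit, fell from 864 ± 56.8 in parental cells to 5.18 ± 2.99, a background level, in resistant cells. Its log2 difference of -5.38 ± 0.27 (adjusted p = 3.82e-11) rests on the pseudocount and ran from -7.23 to -3.62 over the other settings.

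Other genes with large falls served varied functions. The log2 differences were -5.29 ± 0.29 for the testis antigen SPANXB1, -3.96 ± 0.33 for the centriole protein CETN2, and -3.71 ± 0.26 for CDH11, a cadherin of mesenchymal cells. They were -3.62 ± 0.28 for the natriuretic peptide NPPB, -3.46 ± 0.36 for cytidine deaminase, CDA, and -3.27 ± 0.31 for the phospholipase PLCB4. With low signals in resistant cells the sizes of these falls rest on the setting, running from -5.24 to -2.65 for CETN2, -4.34 to -2.37 for CDA and -5.03 to -1.92 for PLCB4. PRSS2, a trypsinogen gene, had a difference of -4.81 ± 0.33. The PRSS2 and CDH11 probe sets are of a type that can also bind other transcripts, and the SPANX genes are nearly alike in sequence, so the gene measured there is uncertain. Among the genes that rose were ID3 (3.75 ± 0.21), a dominant negative partner of basic helix-loop-helix factors, and the histone genes H1-2 (3.74 ± 0.12) and H2AC6 (3.48 ± 0.12). In the gene order of assembly GRCh38.p14, with dimmer genes skipped, these histone genes lie in a run of 15 genes on chromosome 6, from TRIM38 to ABT1. Of these 15 genes 10 were called higher in resistant cells, and the run had a mean log2 difference of 1.40. SPANXB1 is the first of 15 on chromosome X, up to SSR4, of which 12 were called lower, with a mean of -1.02. These runs, like those named below, leave out the dimmer genes between their members. They were chosen by their means, which are therefore too large.

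Of the 29 gene lists fixed before the data were examined, 10 shifted between resistant and parental cells in limma's camera test, 3 up and 7 down, and 8 of these calls held with an estimated correlation between genes. The antigen presentation list had the smallest p, with a median log2 difference of 1.11 (adjusted p = 3.01e-21, and 0.00106 with an estimated correlation). Of its 22 measured genes 17 rose, 1 fell and 4 did not pass, and adjusted over the list alone 19 rose and 1 fell. The class II genes HLA-DRB1 (2.38 ± 0.10), HLA-DPA1 (2.37 ± 0.10) and HLA-DPB1 (2.34 ± 0.12), which encode chains that present peptides to helper T cells, and the immunoproteasome subunit PSMB9 (1.61 ± 0.09) led it. These genes also lie in a run of 15 neighbouring genes on chromosome 6, from HLA-DRA to COL11A2, of which 10 were called higher, and HLA-DRB1 probes can bind transcripts of related class II genes. Of 42 interferon-stimulated genes 13 rose and 1 fell, the same counts as when adjusted over the list alone, with LGALS3BP (1.05 ± 0.08), GBP2 (0.58 ± 0.08) and IFIT3 (0.72 ± 0.10) first (adjusted p of the list = 0.000165). Of 29 oxidative phosphorylation genes 9 rose and 4 fell, and 12 rose and 6 fell adjusted over the list alone. COX5A rose by 0.89 ± 0.08 and COX7B, like it a subunit of cytochrome c oxidase, fell by 0.67 on the log2 scale. That list's call (adjusted p = 0.0175) was lost with an estimated correlation (adjusted p = 0.389 with an estimated correlation), without parental replicate 1 (0.114) and without resistant replicate 2 (0.0645).

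Genes of cholesterol synthesis were lower in resistant cells: of 18 measured, 13 fell and 1 rose, and 14 fell and 1 rose adjusted over the list alone (adjusted p of the list = 9.08e-10). They included the sterol oxidase MSMO1 (-1.31 ± 0.09), the late enzyme DHCR7 (-1.04 ± 0.09) and the sterol sensor partner INSIG1 (-1.25 ± 0.13). Of 30 epithelial genes 11 fell and 2 rose, and 12 fell and 2 rose adjusted over the list alone (adjusted p of the list = 4.47e-06). The desmosome plaque protein DSP fell by 3.08, and the keratins KRT19 and KRT7 had log2 differences of -1.75 ± 0.09 and -1.81 ± 0.10; the other KRT7 probe set had the opposite sign without passing. Of 17 luminal breast markers, chosen as markers of other breast lines, 4 fell and 1 rose, also adjusted over the list alone (adjusted p of the list = 0.00822), led by KRT19, KRT8 (-1.74 ± 0.10) and KRT18 (-2.12 ± 0.12). KRT7, KRT8 and KRT18 lie within 15 neighbouring genes on chromosome 12, of which 10 were called lower, with a mean of -0.88.

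Inflammatory cytokines and NF-kB targets also shifted down (adjusted p = 0.000233), with 12 of 28 lower and 2 higher, and 14 lower and 2 higher adjusted over the list alone. IL6 went from 2118 to 694 in mean signal (log2 difference -1.58 ± 0.10), IL24 had a difference of -2.55 ± 0.19, and CXCL8, a neutrophil attractant, of -1.53 ± 0.15. Of 26 hypoxia and glycolysis genes 13 fell and 1 rose, and 14 fell and 1 rose adjusted over the list alone (adjusted p of the list = 3.68e-05). The glycolytic enzyme TPI1 (-1.19 ± 0.07), the angiogenic factor VEGFA (-1.50 ± 0.10) and BNIP3 (-1.24 ± 0.10) led it. In the unfolded protein and integrated stress response list 11 of 25 fell and 3 rose, and 13 fell and 4 rose adjusted over the list alone (adjusted p of the list = 0.00278). Asparagine synthetase, ASNS, fell by 2.03 on the log2 scale, the pseudokinase TRIB3 by 0.98 and ATF3 by 1.51, whereas the chaperone HSP90B1 rose by 0.79 ± 0.09. Of 8 metallothioneins 4 fell, and 7 adjusted over the list alone (adjusted p of the list = 0.00157, and 0.111 with an estimated correlation). MT1E differed by -0.69 ± 0.11, and probes of this family bind its members alike.

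Genes tied to taxane resistance in other cells gave mixed results. The transporter gene ABCB1, whose product exports paclitaxel, had a log2 difference of -0.04 ± 0.36 (95% interval -0.80 to 0.71). That interval is on the scale with the pseudocount, which understates changes of dim genes. As the ABCB1 signal is dim, changes within the interval, and larger folds in the signal itself, stay open. ABCG2, another exporter, rose by 0.78 ± 0.16 (adjusted p = 0.00211), and ABCC1 differed by 0.13 ± 0.10 (adjusted p = 0.516). Among tubulins TUBB2A rose by 0.90 ± 0.14, TUBB6 fell by 0.56 and TUBA1A by 0.68, while TUBB3 differed by 0.19 ± 0.10 (adjusted p = 0.24). The microtubule destabiliser STMN1 differed by -0.30 (adjusted p = 0.189) and the stabiliser MAPT by -0.11 (adjusted p = 0.91). The tubulin list as a whole gave an adjusted p of 0.834, and the efflux transporter list one of 0.267. The cell cycle inhibitor CDKN1A rose by 1.40 ± 0.14 and the retinoid X receptor gene RXRA by 0.80 ± 0.11. The retinol-metabolising DHRS3 rose by 2.12 ± 0.23 (adjusted p = 1.97e-06), from 1.32 to 2.73 over the other settings.

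The other lists were not called in resistant against parental cells. The adjusted p was 0.97 for microtubule regulators, 0.782 for retinoic acid receptor targets, 0.673 for liver X receptor targets and 0.669 for PPAR targets. It was 0.1 for S phase genes, 0.93 for mitosis genes, 0.782 for apoptosis regulators, 0.358 for p53 targets and 0.349 for mesenchymal genes. Matrix proteases and NRF2 targets each gave 0.103, ribosomal proteins 0.14, cancer-testis antigens 0.154 and breast stem cell markers 0.304. Markers of other cell types gave 0.57 for blood cells and 0.981 for fibroblasts. In the TGF-beta and YAP target list (adjusted p = 0.566) 8 genes rose and 6 fell, with a median of -0.10 and a mean of 0.17. In each list called in the 5 comparisons the median, the mean and the test had the same sign, whereas some lists not called had mixed signs, such as mitosis genes with a median of 0.05 and a mean of -0.04 here.

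In all, 3200 of 22215 probe sets differed between resistant and parental cells at an adjusted p below 0.05, 1575 higher and 1625 lower, and 764 of them by at least 2-fold. With median centring 1694 were higher and 1352 lower. Arrays also differed in the brightness of their hybridisation spike-in controls, which was 10.8 ± 0.44 (log2, SD, n = 4) in parental cells and 10.4 ± 0.07 in resistant cells, so that 1 parental array and all 4 resistant arrays fell among the 9 dimmer ones. Within those 9 arrays 1951 probe sets differed, where the lone parental array is assumed to vary like the other groups. That lone parental array was replicate 1, flagged below for its actin control ratio. The 7 brighter arrays held no resistant array.

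**Figure D1:**
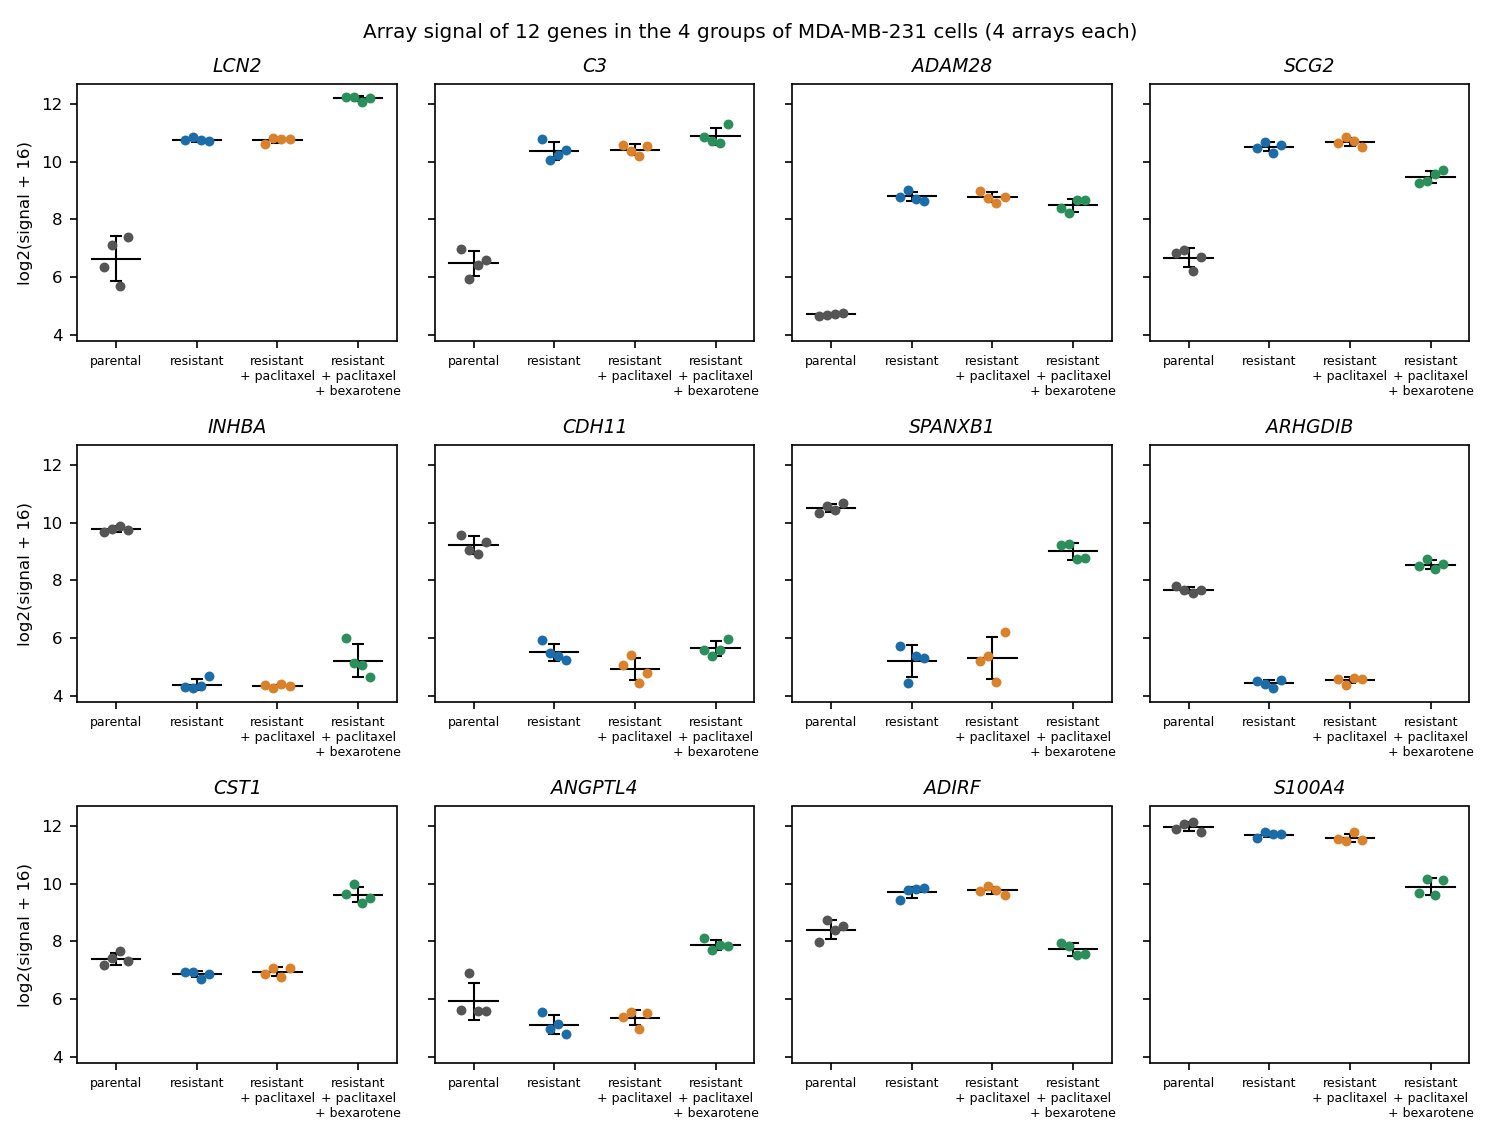
Signal of 12 genes on the log2(signal + 16) axis in parental, resistant, paclitaxel-treated resistant and paclitaxel-plus-bexarotene-treated resistant cells; each point is 1 array, the horizontal bar the group mean and the whiskers the SD (n = 4). LCN2, C3, ADAM28 and SCG2 were higher in resistant than in parental cells, INHBA, CDH11, SPANXB1 and ARHGDIB lower, and ARHGDIB went from a background level of 7.28 in mean signal with paclitaxel alone to 360 with bexarotene plus paclitaxel.

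The next question was what continued paclitaxel changed in cells that already resisted it. A single probe set passed, that of PLEKHA1, a phosphoinositide-binding adaptor, with a log2 difference of -1.73 ± 0.26 between paclitaxel-treated and untreated resistant cells (adjusted p = 0.0459 in limma). PLEKHA1 falls outside the fixed naming rule and is named after its values were seen. LCN2 had a mean signal of 1699 with paclitaxel and 1723 without, SCG2 of 1622 and 1458, and INHBA, at background in both, of 4.35 and 5.18. Of the genes fixed in advance, ABCB1 differed by -0.10 ± 0.36, TUBB2A by -0.34 ± 0.14, CDKN1A by -0.14 ± 0.14 and BIRC5, an inhibitor of apoptosis active in mitosis, by 0.06 ± 0.10, none past the threshold.

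No gene list was called. The smallest adjusted p was 0.0536, for oxidative phosphorylation genes with a median log2 difference of -0.05, followed by 0.238 for metallothioneins; mitosis genes had a median of 0.04 (adjusted p = 0.754) and p53 target genes one of -0.02 (adjusted p = 0.822). Without adjustment 1629 probe sets had p below 0.05, where 1110.75 were expected by chance. On simulated data in this comparison 53.6% of 2-fold changes and 24.8% of 1.5-fold changes were recovered, so changes of under 2-fold would mostly have been missed. Those simulations planted 200 changes of up to 8-fold, which eases the adjusted threshold, and used independent noise. Recovery in the real comparison could therefore be lower. With each array left out in turn the count was 11 without bexarotene replicate 4, 3 without parental replicate 1, 2 without parental replicate 3 or 4 or paclitaxel replicate 1, 1 without resistant replicate 2, and 0 without any other array. In the same way 2 lists were called without resistant replicate 4 and 1 without resistant replicate 1, paclitaxel replicate 1, 2 or 3, or bexarotene replicate 1. It was 2 within the 9 dimmer arrays, which held 1 paclitaxel array, and the 7 brighter arrays held no resistant array.

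The main treatment question was how bexarotene changed resistant cells that stayed on paclitaxel. ARHGDIB, a gene expressed mostly in blood cells, rose from a mean signal of 7.28 ± 1.65 (SD, n = 4) with paclitaxel to 360 ± 36.9 with both drugs, a log2 difference of 4.01 ± 0.20 (adjusted p = 3.3e-10). As the signal with paclitaxel is at background, the size of that difference rests on the pseudocount and ran from 2.57 to 5.47 over the other settings. SPANXB1 rose by 3.69 ± 0.29, the cystatin CST1 by 2.67 ± 0.15 and KISS1, which encodes the kisspeptin peptides, by 2.34 ± 0.35 (1.39 to 3.24 over the other settings). NPPB rose by 2.28 ± 0.28, CDA by 2.19 ± 0.36 (1.20 to 3.26) and the actin-bundling protein LCP1 by 2.03 ± 0.14. The adipogenesis regulator ADIRF went from 858 ± 78.9 to 197 ± 31.7, a log2 difference of -2.05 ± 0.14, and the secretory chaperone SCG5 differed by -1.92 ± 0.13. The calcium-binding proteins S100A2 and S100A4 differed by -1.74 ± 0.08 and -1.68 ± 0.12, glycogen phosphorylase PYGB by -1.86 ± 0.35 and OLFML2A by -1.72 ± 0.14. Chemerin, RARRES2, differed by -1.63 ± 0.31 and the cytokine CTF1 by -1.58 ± 0.27 (-2.08 to -0.93 over the other settings).

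Targets of the receptors that pair with retinoid X receptors shifted up as lists, although only the PPAR call held in every setting. Of 19 measured PPAR targets 6 rose and 1 fell, and 12 rose and 1 fell adjusted over the list alone (adjusted p of the list = 1.23e-05, and 0.016 with an estimated correlation). ANGPTL4, an inhibitor of lipoprotein lipase, rose by 2.52 ± 0.30 (1.67 to 3.10 over the other settings). The lipid droplet protein PLIN2 rose by 1.71 ± 0.12 (0.88 to 1.79), and TXNIP fell by 0.81. Of 14 retinoic acid receptor targets 2 rose, and 4 adjusted over the list alone (adjusted p of the list = 0.0128, and 0.088 with an estimated correlation). CYP26B1, which degrades retinoic acid, rose by 1.96 ± 0.46, a call lost without paclitaxel replicate 3 (adjusted p = 0.0536), with a pseudocount of 1 (0.0611) and with spike-in brightness as a covariate (0.0839). TINAGL1 rose by 0.69 ± 0.18, a call lost without paclitaxel replicate 1 or 3 or bexarotene replicate 2 or 4 (adjusted p from 0.0656 to 0.102), while CYP26A1 differed by 0.97 ± 0.33 (adjusted p = 0.0992). The list's own call was lost without paclitaxel replicate 1 (adjusted p = 0.105) and without the 40% dimmest probe sets (0.0643). Of 14 liver X receptor targets 3 rose, and 4 adjusted over the list alone (adjusted p of the list = 0.0136, and 0.066 with an estimated correlation). That call was also lost without the 2 arrays of highest 18S ribosomal RNA signal (adjusted p = 0.0546). They were the desaturase SCD (0.77 ± 0.08), the cholesterol exporter ABCA1 (1.22 ± 0.22; another of its probe sets had the opposite sign without passing) and APOC1 (0.77 ± 0.18). RXRA fell by 0.60 on the log2 scale (adjusted p = 0.00153), and RXRB, RXRG, RARB, ABCG1 and SREBF1 did not pass, with differences of 0.03, 0.23, -0.05, 0.03 and -0.30. DHRS3 (0.32, adjusted p = 0.549) and transglutaminase TGM2 (0.13, adjusted p = 0.519) did not pass either.

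The mitosis and S phase lists shifted up with bexarotene, though most of their members did not pass over all probe sets. Of 35 mitosis genes 11 rose and none fell, and 19 rose and 1 fell adjusted over the list alone (adjusted p of the list = 2.71e-09), with a median log2 difference of 0.24. They were led by the anaphase activator CDC20 (0.57 ± 0.09), the checkpoint protein MAD2L1 (0.76 ± 0.12) and the kinetochore protein NDC80 (0.71 ± 0.13). Of 33 genes of the S phase 8 rose and none fell, and 11 rose and 1 fell adjusted over the list alone (adjusted p of the list = 0.000264), led by the ribonucleotide reductase subunits RRM2 (0.66 ± 0.09) and RRM1 (0.39 ± 0.07). BIRC5 rose by 0.36 ± 0.10 (adjusted p = 0.0314), a call lost without paclitaxel replicate 1 or any single bexarotene replicate (adjusted p from 0.0526 to 0.0914).

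The epithelial list shifted up and the mesenchymal list down, though most of their members did not pass. Of 30 epithelial genes 8 rose and none fell, and 10 adjusted over the list alone (adjusted p of the list = 0.000296), with DSP (1.45 ± 0.15), KRT18 (1.01 ± 0.12) and KRT8 (0.56 ± 0.10) first. Of 29 mesenchymal genes 5 fell and none rose, and 6 fell adjusted over the list alone (adjusted p of the list = 0.00284). Besides S100A4 these included fibronectin, FN1 (-1.42 ± 0.11), and the collagen COL5A1 (-1.29 ± 0.15). CDH1 and VIM, the common markers of the epithelial and mesenchymal states, differed by 0.03 ± 0.29 and -0.28 ± 0.11 and did not pass. In the TGF-beta and YAP target list 8 of 25 fell and 1 rose, and 10 fell and 3 rose adjusted over the list alone (adjusted p of the list = 0.00166). The receptor TGFBR2 differed by -0.73 ± 0.08 and BMP4 by -0.89 ± 0.14, and TGFBI rose by 0.66 ± 0.08.

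Of 28 inflammatory genes 5 rose and 1 fell, also adjusted over the list alone (adjusted p of the list = 0.0136), with the interleukins IL1B (1.51 ± 0.11) and IL1A (1.89 ± 0.18) and the chemokine CXCL2 (1.42 ± 0.14) up and IL6 down by a log2 difference of -0.75 ± 0.10. Of 8 metallothioneins 6 rose, also adjusted over the list alone (adjusted p of the list = 1.13e-07), among them MT1E (0.69 ± 0.11). Of 18 cholesterol synthesis genes 5 rose, and 6 rose and 1 fell adjusted over the list alone (adjusted p of the list = 0.00106), including MSMO1 (0.64 ± 0.09) and DHCR7 (0.53 ± 0.09). Interferon-stimulated genes shifted slightly down (adjusted p = 0.0189), with 3 of 42 lower and 1 higher, and 4 lower and 2 higher adjusted over the list alone. IFIT1, which binds viral RNA, differed by -0.71 ± 0.15, while ISG15 (-0.10 ± 0.13) and IFI27 (-0.30 ± 0.11) did not pass. The IFIT1 call was lost without the 2 arrays of highest 18S ribosomal RNA signal (adjusted p = 0.0583). The list's call was lost with median centring, with spike-in brightness as a covariate, without the 2 arrays of highest 18S ribosomal RNA signal and without bexarotene replicate 4 (adjusted p = 0.0665). Of 22 antigen presentation genes 5 rose, and 6 adjusted over the list alone (adjusted p of the list = 0.0319, and 0.311 with an estimated correlation), with HLA-DPA1 up by 0.79 ± 0.10. This call was also lost without paclitaxel replicate 1 (0.308) or bexarotene replicate 4 (0.0926), with replicate number as a block (0.0519), with quantile normalisation (0.22), without the dimmest probe sets (0.109) and without the arrays of highest 18S signal (0.0593). Of 29 oxidative phosphorylation genes 4 rose, and 5 adjusted over the list alone (adjusted p of the list = 0.0136, and 0.354 with an estimated correlation), with NDUFA9 up by 0.57 ± 0.11, and without paclitaxel replicate 1 the adjusted p was 0.176. Altogether 14 lists were called, 11 up and 3 down, 10 of them with an estimated correlation.

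In total 1276 probe sets differed between the bexarotene and the paclitaxel arrays, 686 higher and 590 lower, and 178 by at least 2-fold. Centring each array on its median, a shift of 0.08 between the groups on the log2 scale, gave 934 higher and 323 lower. The paclitaxel arrays were brighter in spike-in signal (10.9 ± 0.42 against 10.4 ± 0.45). Within the 9 dimmer arrays, with 3 bexarotene and 1 paclitaxel array, 519 probe sets differed, and within the 7 brighter arrays, with 1 and 3, 401 did, where each lone array is assumed to vary like the other groups. Without the 2 arrays of highest 18S signal the count was 798. The lone paclitaxel array among the dimmer ones was replicate 1, flagged below for its GAPDH control ratio. The lone bexarotene array among the brighter ones was replicate 4, which had the highest 18S signal. Mean 18S signal was 9.97 ± 1.55 with bexarotene and 10.9 ± 0.84 with paclitaxel.

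**Figure D2:**
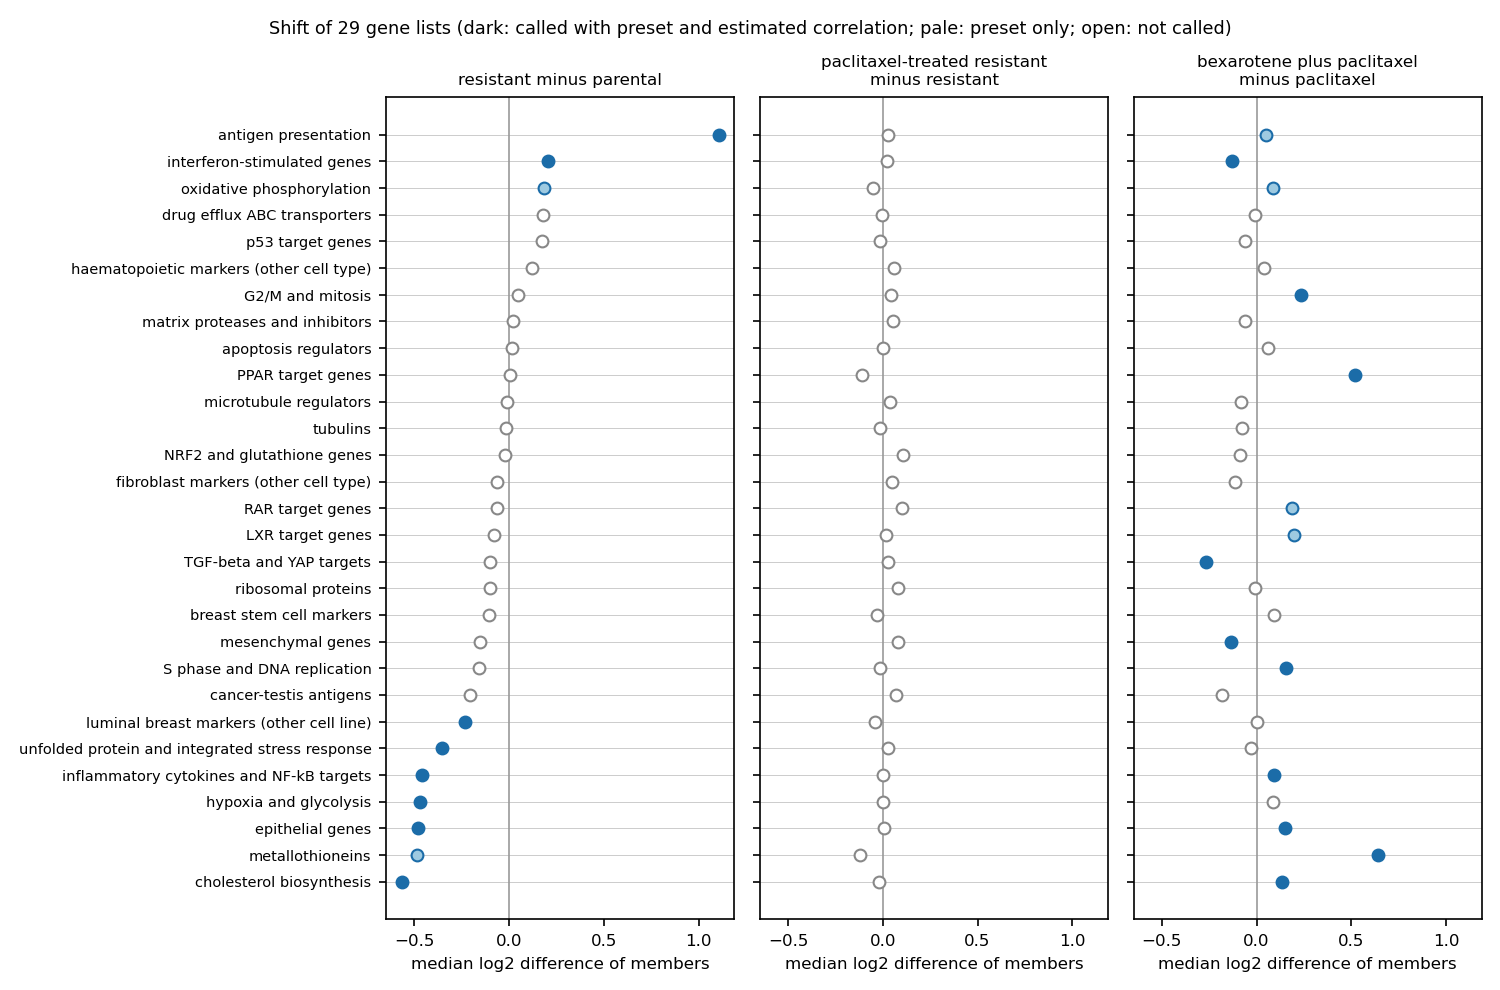
Median log2 difference (horizontal axis) of the measured members of 29 gene lists (vertical axis) in resistant minus parental, paclitaxel-treated minus untreated resistant, and bexarotene plus paclitaxel minus paclitaxel; each circle is 1 list, dark blue when called by camera with preset and with estimated correlation, pale blue when called with the preset correlation alone, open when not called. The antigen presentation list stood at 1.11 in resistant minus parental, no list was called in the middle panel, and the metallothionein list stood at 0.64 in the right panel.

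Because the series asks about re-sensitisation, the genes that differed in resistant cells were followed under bexarotene, in arrays that the 2 comparisons do not share. Of 2047 such genes 442 also changed with bexarotene. Among these, 205 had been lower and rose, 151 had been higher and fell, 45 had been higher and rose further, and 41 had been lower and fell further. With independent calls 39.0, 33.1, 40.01 and 32.3 genes would be expected. Genes that rose after being lower included ARHGDIB, SPANXB1, NPPB, CDA and CETN2 (1.97 ± 0.33). SCG2 (-1.21 ± 0.14), ID3 (-1.09 ± 0.21), H1-2 (-0.66 ± 0.12) and CYTIP (-0.70 ± 0.15) fell after being higher. LCN2 went the other way and rose further, to a mean signal of 4673 ± 241 (log2 difference 1.45 ± 0.23). INHBA had a signal of 23.6 ± 17.2 against 864 in parental cells and did not pass (adjusted p = 0.0643). C3, ADAM28, H2AC6, PRSS2, PLCB4 and CDH11 did not pass either.

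Over all 2047 genes 65.9% had opposite signs, which the exact permutation test of the 8 array labels did not separate from chance (two-sided exact p = 0.0857, 70 arrangements). An arrangement that exchanged paclitaxel replicate 4 and bexarotene replicate 2 gave 68.0%; the arrays it took as bexarotene had 18S signal higher by 0.66 on average. The correlation of the differences across genes, which are not independent replicates, was -0.41. Its two-sided exact permutation p was 0.0286, the smallest that 70 arrangements can give. These arrangements took the arrays as unpaired, although many arrays correlated best with those of their own replicate number. Within the 9 dimmer arrays the share was 59.5% and the correlation -0.28, where the exact p cannot fall below 0.25, and the 7 brighter arrays held no resistant array. The p of the correlation rose to 0.0571 with a pseudocount of 64 and with replicate number as a block (correlation -0.40), to 0.143 without parental replicate 1, and to 0.0571 without paclitaxel replicate 1 or any single bexarotene replicate, while the correlation itself ran from -0.45 to -0.37 over all arrays left out in turn.

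**Figure D3:**
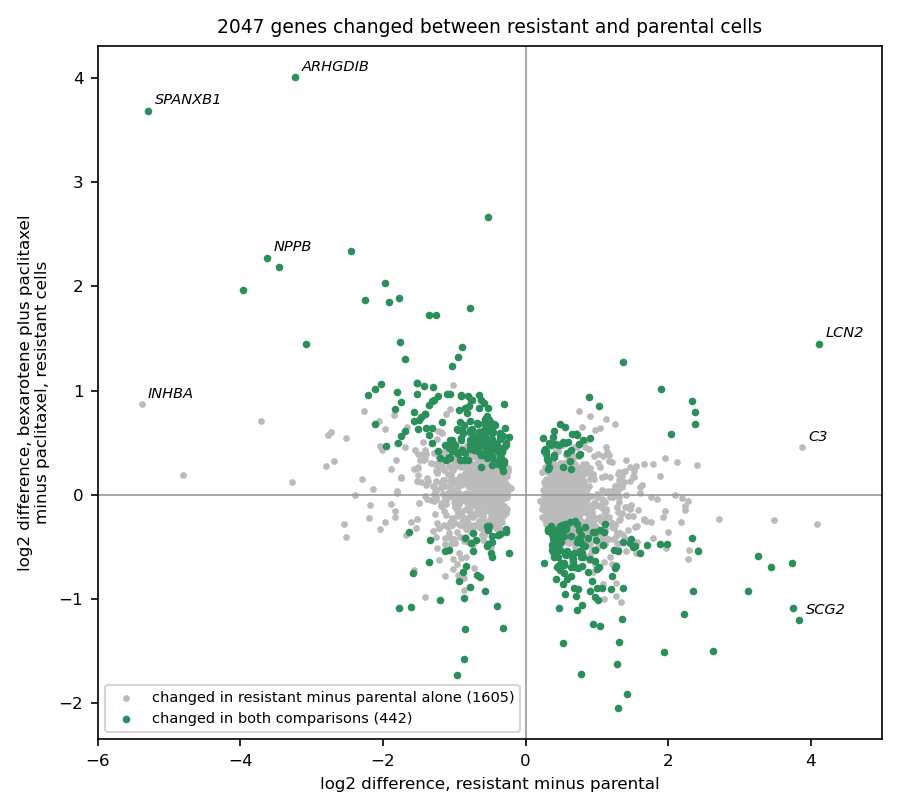
Log2 difference between bexarotene plus paclitaxel and paclitaxel (vertical axis) against the log2 difference between resistant and parental cells (horizontal axis) for the 2047 genes changed in the latter; each point is 1 gene, green for the 442 genes changed in both comparisons and grey for the rest. Most green points lie in the upper left and lower right corners, with LCN2 an exception in the upper right.

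Against untreated resistant cells, cells given bexarotene and paclitaxel differed much as they did against paclitaxel alone; these comparisons share the bexarotene arrays, so their likeness is not independent evidence. ARHGDIB (4.10 ± 0.20), SPANXB1 (3.79 ± 0.29), CYP26B1 (3.00 ± 0.46) and ANGPTL4 (2.76 ± 0.30) rose. The sizes of these rises rest on the setting, running from 2.60 to 5.75 for ARHGDIB and 1.77 to 3.53 for ANGPTL4. ADIRF (-1.99 ± 0.14), SCG5 (-1.99 ± 0.13), S100A2 (-1.94 ± 0.08) and RARRES2 (-1.86 ± 0.31) fell. TUBB2A differed by -0.82 ± 0.14 (adjusted p = 0.00146) and CDKN1A by -0.56 ± 0.14 (adjusted p = 0.024, but from 0.0706 to 0.095 without resistant replicate 1 or 2 or bexarotene replicate 2, 3 or 4, 0.0686 with median centring and 0.088 without an intensity trend). The count was 779 probe sets, 400 higher and 379 lower, 123 of them by at least 2-fold. With median centring it was 424 higher and 234 lower, within the 9 dimmer arrays 889 differed, and without bexarotene replicate 2 the count was 514.

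Of the 29 lists 14 were called, 11 up and 3 down, and 13 with an estimated correlation. Mitosis genes had the smallest p (adjusted p = 6.21e-14), with 9 of 35 higher and 18 adjusted over the list alone, led by CDC20 (0.61 ± 0.09), MKI67 (0.68 ± 0.13) and BUB1B (0.60 ± 0.12). The MKI67 call was lost with the mean of all its probe sets (0.46, adjusted p = 0.0836). Retinoic acid receptor targets (adjusted p = 5.57e-05, 3 of 14 higher, the same adjusted over the list alone) and liver X receptor targets (adjusted p = 0.00739, 2 of 14 higher and 3 adjusted over the list alone) were called with either correlation here. Markers of blood cells were called up as a list (adjusted p = 0.0254). LCP1 (1.77 ± 0.14) was the single member of 16 that passed, also adjusted over the list alone. The list's call was lost without resistant replicate 4 (adjusted p = 0.0509). Antigen presentation was called with the preset correlation (adjusted p = 0.00251, but 0.129 with an estimated correlation and 0.0746 with quantile normalisation), with 5 of 22 genes higher and 7 adjusted over the list alone.

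Set against parental cells, the cells given both drugs still differed widely. LCN2 was 46.9-fold higher, at a log2 difference of 5.55 ± 0.23, and C3 (4.39 ± 0.19), ADAM28 (3.78 ± 0.13, from 1.86 to 4.95 over the other settings) and HLA-DPA1 (3.19 ± 0.10) were also higher. PRSS2 (-4.71 ± 0.33), INHBA (-4.56 ± 0.27), CDH11 (-3.58 ± 0.26) and IL24 (-2.96 ± 0.19) were lower. Antigen presentation genes were higher (18 of 22, also adjusted over the list alone; adjusted p = 3.5e-29), cholesterol synthesis genes lower (10 of 18, and 12 adjusted over the list alone; adjusted p = 5.66e-07) and hypoxia and glycolysis genes lower (13 of 26 with 1 higher, and 15 and 1 adjusted over the list alone; adjusted p = 3.65e-06). The mitosis list shifted up (adjusted p of the list = 1.09e-06), led by TOP2A (0.77 ± 0.11). In it 15 of 35 genes were higher, and 22 with 3 lower adjusted over the list alone. The metallothionein list gave an adjusted p of 0.912.

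Of 13 lists called, 6 up and 7 down, 7 were called with an estimated correlation. With it the adjusted p was 0.0521 for epithelial genes and for the unfolded protein response list, 0.077 for blood cell markers, 0.106 for NRF2 targets, 0.115 for PPAR targets and 0.19 for oxidative phosphorylation. The count was 2544 probe sets, 1230 higher and 1314 lower, 575 of them by at least 2-fold. With median centring 1606 were higher and 914 lower. Within the 9 dimmer arrays, with 1 parental array, 1396 differed, and within the 7 brighter arrays, with 1 bexarotene array, 1214 did.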

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

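The spread of single arrays was compared by a rule fixed in advance, while the count without the arrays of highest 18S signal was chosen only after the result was seen. In 88 groups of 4 values, 9 held an array far from the other 3, where chance gives about 4.4. For actin, the log2 ratio of 3' to 5' control signal, a measure of RNA degradation, was 0.70 in parental replicate 1, and the nearest parental array had 0.27. This ratio was also highest in replicate 1 among the resistant (0.66) and the paclitaxel arrays (0.72). The deviations of these 3 arrays from their group means correlated at 0.33 to 0.61 across the probe sets brighter than the median, which are not independent replicates. For GAPDH the same ratio was 0.44 in paclitaxel replicate 1, and the nearest had 0.15. The log2 signal of H1-2 was 11.08 in resistant replicate 1, lower than in the other resistant arrays, the nearest at 11.29. CYTIP was at 5.71 in parental replicate 1, with the nearest at 5.37, and INHBA at 4.68 in resistant replicate 4, with the nearest at 4.33. PLCB4 was at 5.34 in resistant replicate 3, with the nearest at 4.30. ARHGDIB was at 4.38 in paclitaxel replicate 2, below the nearest at 4.58, and NPPB at 7.81 in bexarotene replicate 3, below the nearest at 8.09. CDA was at 5.85 in paclitaxel replicate 1, with the nearest at 4.56.

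The control probe sets for 18S ribosomal RNA, which enter no comparison, were brighter in 3 treated arrays than in any parental array, whose highest log2 signal was 10.9642. They reached 10.9674 in paclitaxel replicate 3, 11.92 in paclitaxel replicate 4 and 12.27 in bexarotene replicate 4. Without the last 2 of these arrays 798 probe sets differed between bexarotene plus paclitaxel and paclitaxel, 459 higher and 339 lower.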

How the results depend on the processing

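The settings with spike-in brightness and with 18S signal were chosen only after the result was seen. Of 208 calls on named genes, recomputed 6027 times, 5857 kept their direction and side of the threshold, 168 were lost and 2 reversed. Many of these genes were named for large differences or small p in the same data, which favours keeping a call. Leaving out an array of a group not compared changes the error of a difference but not the difference itself. Of 51 list calls, recomputed 1326 times, 1278 were kept and 48 lost. Calls were also gained. Of 103 gene results not called, 19 gained a call in some setting, 40 times in all. Of 94 list results not called, 28 did so, 71 times in all. With the mean of all probe sets per gene, NDUFA2 reversed to -0.056 in resistant against parental cells and TGM2 to -0.063 in bexarotene plus paclitaxel against parental cells, where another probe set of each gene had the opposite sign. With spike-in brightness as a covariate the ribosomal protein list's median turned to -0.12 in paclitaxel-treated against untreated resistant cells and to 0.19 in bexarotene plus paclitaxel against parental cells. In paclitaxel-treated against untreated resistant cells the count of 1 probe set became 2 with quantile normalisation, 5 with a pseudocount of 64, 4 without the 40% dimmest probe sets, 4 with array weights and 4 with 1 probe set per gene. It became 0 with the replicate block, 0 in a fit of the groups compared, 2 with the spike-in covariate, 2 in the dimmer arrays and 2 without the arrays of highest 18S signal. The number of lists called there went from 0 to 1 with median centring, 1 with a pseudocount of 64, 1 with the replicate block and 3 with the spike-in covariate. The arrays share a replicate number without a stated pairing. Across the probe sets brighter than the median, 11 of 24 same-number pairs had deviations correlated above 0.1. Among arrays of other groups, 11 of 16 arrays correlated best with their own number. The replicate block gave 3585, 1564, 990 and 2899 probe sets in the other comparisons, in the order resistant against parental, then bexarotene plus paclitaxel against paclitaxel, resistant and parental cells. Without an intensity trend 843 differed between bexarotene plus paclitaxel and paclitaxel, and 441 against resistant cells, where array weights gave 1432. The dimmer arrays gave 1951 in resistant against parental cells, and 519 and 1396 for bexarotene plus paclitaxel against paclitaxel and parental cells, and the brighter arrays gave 401 and 1214 for the latter pair. Leaving out the arrays of highest 18S signal gave 798 for bexarotene plus paclitaxel against paclitaxel. An estimated correlation left 7 lists called in bexarotene plus paclitaxel against parental cells, and fry, which does not compare a list with other genes, called 19 in resistant against parental cells. With each array left out in turn, the counts ran from 2694 to 3511, 0 to 11, 860 to 1466, 514 to 900 and 2040 to 2822 probe sets, with the paclitaxel comparison second and the others in the order above; the extremes of 11 and 514 came without bexarotene replicate 4 and without bexarotene replicate 2. The lists called ran from 9 to 12, 0 to 2, 11 to 15, 13 to 16 and 12 to 15, and 2 was reached without resistant replicate 4. The share of genes with opposite signs ran from 63.7% to 68.4% and missed the threshold in each setting, as it did with all arrays; the replicate block gave 65.2%, and took the correlation of the differences from -0.41 to -0.40, where it missed the threshold (exact permutation p = 0.0571). Except where the construction of the setting shows it, the cause was not tested. Probe sets with signals near the background limit what can be seen of weakly expressed genes such as ABCB1.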

Other observations

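The tests of copy number, of parental cells mixed in and of power, and the settings with spike-in brightness, were chosen only after the result was seen, as were the genes named in the next paragraphs. Alongside ID3, its relatives ID1 (log2 difference 3.26 ± 0.12) and ID2 (3.12 ± 0.18), which also block basic helix-loop-helix factors, were higher in resistant than in parental cells, and both fell with bexarotene plus paclitaxel against paclitaxel, with differences of -0.59 ± 0.12 and -0.92 ± 0.18. The protease genes CTSB (0.96 ± 0.09) and CTSD (1.12 ± 0.11), which encode cathepsins B and D, and the metalloprotease inhibitor TIMP1 (1.35 ± 0.12) rose in resistant cells, while the matrix protease list as a whole was not called (adjusted p = 0.103). The death ligand gene TNFSF10 (0.92 ± 0.08) and the caspase gene CASP8 (0.88 ± 0.10) rose and the receptor gene TNFRSF10B fell by 0.60 on the log2 scale, while the apoptosis regulator list as a whole was not called (adjusted p = 0.782).

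Single markers of other cell types also moved. CD14, a co-receptor of monocytes, LUM, a proteoglycan of connective tissue, and LAPTM5, a lysosomal protein of blood cells, had log2 differences of 2.41 ± 0.19, 2.20 ± 0.25 and 0.61 ± 0.10 in resistant against parental cells. LCP1, another blood cell marker, fell by 1.97 there and rose by 2.03 ± 0.14 with bexarotene, so the markers went both ways. Fibronectin, FN1, rose by 0.53 ± 0.11 in resistant cells before its fall with bexarotene. The pluripotency factor KLF4 rose by 1.09 ± 0.14 with bexarotene plus paclitaxel against paclitaxel, and the laminin receptor subunit ITGA6 fell by 0.95.

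Other splits of the 8 arrays in each comparison asked whether the counts depend on the real labels. For resistant against parental cells 1 of 35 splits, the real one, gave as many as 3200 probe sets, and the highest other gave 1. The real split was also the single 1 of 35 for bexarotene plus paclitaxel against paclitaxel (1276, highest other 2). The same held against resistant cells (779, highest other 1) and against parental cells (2544, highest other 0). These counts thus depend on the real labels, and 1 of 35 is the smallest share such splits can give. In a mixed split a real group difference widens the spread, which lowers its count. A difference between cultures that did not come from the treatment would give the same picture. For paclitaxel-treated against untreated resistant cells 5 of 35 splits gave 1 probe set or more (real 1, highest other 1), so chance cannot be excluded.

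Genes that lie next to each other differed together between resistant and parental cells, with a correlation of 0.237 across 6855 genes, which are not independent replicates, where the highest of 200 shuffled gene orders gave 0.030 and the highest other split of the arrays 0.205. Array brightness is argued against, as the correlation was 0.234 with spike-in brightness as a covariate, and so are clusters of related genes, as the correlation at a distance of 10 genes without pairs of like symbols was 0.183 (highest shuffled 0.033). The latter was 0.014 in paclitaxel-treated against untreated resistant cells, inside its shuffled range, but 0.049 in bexarotene plus paclitaxel against paclitaxel (highest shuffled 0.026), where next neighbours correlated at 0.117 (highest shuffled 0.036, highest other split 0.090). In paclitaxel-treated against untreated resistant cells, another split gave 0.078 for next neighbours (highest shuffled 0.041). Differences between arrays apart from the labels can thus exceed shuffled orders. No other splits were made at a distance of 10 genes, so the values there lack that check. Of the 90 genes in 6 runs with few like symbols, on chromosomes 12, 13 and X, 94.4% lay on their run's side, a share raised in part by choosing the runs by their mean. Most of these runs lie on chromosome 13. Those from PABPC3 to HMGB1 and from HSPH1 to LHFPL6 were lower in resistant cells. Those from UGGT2 to IRS2 and from COL4A1 to TFDP1 were higher, so the 6 runs need not be separate regions. A candidate explanation is that the selected cells descend from a clone with other copy numbers. It stays a hypothesis beside regulation of whole regions, as no DNA was analysed here. Next neighbours also correlated more with bexarotene than in any other split of those arrays.

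Of the genes changed in resistant cells and again with bexarotene, 80.5% changed in opposite directions. Parental cells mixed into the bexarotene cultures are argued against, since each gene low in resistant cells would then regain a like share of its parental signal. Of 33 genes at least 4-fold higher in parental cells, 10 had regained shares wholly below 0.1 (INHBA 0.022, CDH11 0.033) and 3 wholly above 0.3, with ARHGDIB at 1.94, beyond the parental level. The share of opposite signs was 64.9% with the spike-in covariate against 65.9% without it. Neither share separates from chance in the exact permutation test. Within the 9 dimmer arrays the share was lower, and brightness ran in part with the groups. Array brightness therefore stays open for this pattern. An effect of bexarotene itself, or growth of a subset of cells during 3 months of treatment, could underlie the pattern, and both stay open. In 5 of the 8 runs 12 to 14 of 15 genes moved opposite to their run's side in resistant cells, but 5, 7 and 9 in the others. As 65.9% of all 2047 changed genes had opposite signs, these counts do not show by themselves that neighbours moved together. The HLA-DRA run moved further the same way (mean 0.23).

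Few probe sets differed between resistant cells with and without paclitaxel. Too little power stays open: 53.6% of simulated 2-fold changes were recovered (exact 95% interval 50.5 to 56.7; 56.0% in the first simulation alone) and 24.8% of 1.5-fold changes. Without adjustment 1629 probe sets had p below 0.05 where 1110.75 were expected, so real changes could have been missed. With array brightness as a covariate the count was 2, which argues against brightness hiding many probe sets, but 3 lists were called there in place of 0, and brightness ran in part with the groups, so smaller shifts stay open. How long after the last paclitaxel dose the cells were harvested is not stated, and a response that had ended by then stays open.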
